A study of Mus musculus with 8 samples.

How the data were processed

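Total RNA from 8 samples of mouse bone marrow stromal cells was amplified, labelled with biotin and hybridised to arrays, 1 array per sample. The deposited values are linear intensities, 1 per probe set and array. The submitters' processing notes name RMA and GCRMA, with no versions and without saying which gave these values, and a genome build is not given in the sources used here. The array medians lay within 0.12 of each other on the log2 scale and the arrays' distributions were not identical, so the values were used as deposited after taking log2.

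Samples were grouped by medium and condition from their titles. The centrifuge samples carry a gravity label that reads microgravity, although their titles and descriptions place them on the 1g centrifuge, and the osteoinductive centrifuge sample is described once as in growth medium although it is labelled as osteo-induced. The titles were followed in both cases, so a wrong title would change the comparisons that use these arrays.

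Of 35557 probe sets, 21789 were paired with 1 gene, 1621 with several genes and 12147 were not named by the annotation used here. Of the identifiers of single-gene probe sets 21698 matched the RefSeq gene table of assembly GRCm38.p6, which was used for names only, and 0 symbols were updated. Probe sets with several genes or none stayed out of the gene tests. Of several probe sets of a gene, the one with the highest mean stood for it. Genes were tested if their mean over the 8 arrays lay above the 40th percentile of all probe sets, a log2 intensity of 7.14, which left 13205 of 19938 genes. The probe sets of some listed genes were not analysed here. An older name in a list was read as the gene's present symbol, unless it is itself the present symbol of another gene. This exception was added after the values had been seen, because Loxl2 and C3 had first been read as older names of other genes. It ended 1 of 64 list calls, that of the matrix genes in centrifuge minus ground, and changed no other. Organ markers and sex-linked genes were fitted without the filter, over all 19938 genes, and their p-values were adjusted over those.

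Differential expression was tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on log2 values. Each comparison between 2 conditions, and that between media, came from a fit with condition and medium and no interaction, with 3 residual degrees of freedom. Flight against ground-based arrays was fitted with medium as a covariate and 5 residual degrees of freedom. In the fits with condition and medium the interaction of the 2 served as the error, because each medium and condition has 1 array. In the flight fit the error also held the differences between microgravity and centrifuge and between ground and laboratory. The 2 conditions on each side of that comparison thus counted as repeats, although they are different conditions. P-values were adjusted by Benjamini-Hochberg within each of 6 comparisons, with a threshold of 0.05, two-sided. Differences within a single medium have 1 array on each side and were not tested.

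The names in 28 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01 and adjusted over lists within a comparison. With the correlation estimated from the residuals, none of the 63 list calls over the 6 comparisons held. Within single media, a list's median was set against 10000 random lists of the same size matched on mean expression, as a description of these arrays. Named genes are the 12 highest rises and 12 deepest falls in microgravity minus centrifuge, microgravity minus ground and osteoinductive minus growth, and 5 of each in the other comparisons. They were taken among genes past the threshold whose sign was the same in every difference within a medium or condition, ranked by the smallest of these differences. Places left were filled by the same ranking among genes that did not pass, and predicted genes were not named. Members of the lists were named as examples.

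On simulated arrays with the means and spread of the real genes, 13205 genes and 50 changed genes for each size of change, the flight comparison recovered 96% of genes changed by 1.41-fold and 100% of those changed by 2-fold, and 7.91% of its calls were false. The comparison of media recovered 96% and 100%, with 6.16% false calls. Microgravity against the centrifuge recovered 68% and 100%, with 3.67% false calls. The simulated errors were independent, with the same spread for a gene on all arrays, and there were no other differences between media or conditions. The real arrays need not meet this, so these rates can be too favourable. In microgravity minus centrifuge the real log2 differences of Slc34a2, Mest and Tspan2 were 2.05, 1.05 and 1.08, and these genes did not pass. Principal components were computed on the tested genes. Alternatives were quantile normalization, no filter, a filter at the 60th percentile, every probe set, 32 added before log2, a variance trend, only the arrays compared, no covariate, and each array left out. Organ marker lists, those lists and the fixed lists without the osteoinductive microgravity array, and 2 subsets of arrays were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.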

Results

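Gene expression was measured with single-colour oligonucleotide arrays in mouse bone marrow stromal cells, the adherent marrow cells that can form bone, cartilage and fat cells. The cells were grown on Skelite, a calcium phosphate scaffold, in growth medium or in osteoinductive medium, which directs such cells towards bone formation. Each medium was measured in 4 conditions: microgravity in flight, a 1g centrifuge within the same incubator in flight, incubation units on the ground, and culture dishes in the laboratory. The flight hardware was automated and the ground units were operated by hand, so comparisons between them also differ in that. The 8 arrays thus hold 1 array for each medium and condition, and 13205 genes were tested. The median intensity per array lay between 180.9 and 196.4. Nothing in the labels says that the arrays came from separate cultures or animals, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. Errors are standard errors (SE) of the log2 fold change, and p-values are adjusted values from limma, or from camera for gene lists.

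The largest axis of variation separated the arrays that flew from those that did not. The first principal component held 58.6% of the variance, and the second, which followed the medium, held 25.8%. The 4 flight arrays had values from -29.79 to -9.33 on the first component, and the 4 ground-based arrays had values from 19.36 to 28.09. The growth medium array from the centrifuge lay nearest to the ground-based arrays, at -9.33.

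**Figure D1:**
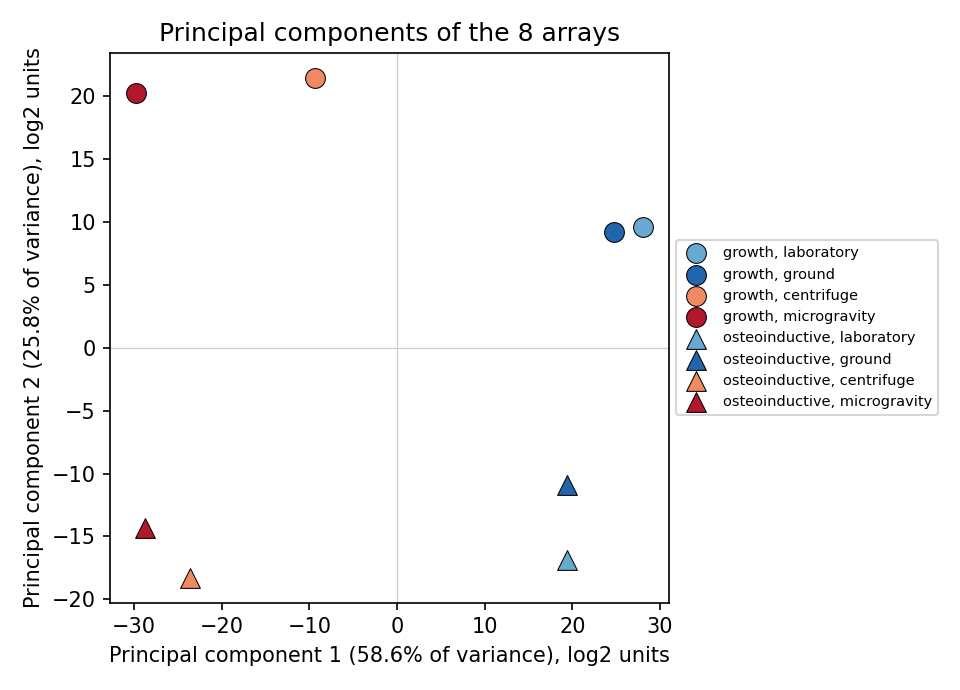
The 8 arrays on the first and second principal components of 13205 genes (log2 units), with circles for growth medium, triangles for osteoinductive medium and colours for the 4 conditions. The flight arrays lie at or below -9.33 on the first component and the ground-based arrays at or above 19.36.

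The comparison of microgravity with the ground hardware asked what changed over the whole flight. Genes of neurons were among the largest rises in microgravity. Gpm6a, a neuronal membrane glycoprotein (probe set 10571815), was 25.3-fold higher (log2 fold change 4.66, SE 0.15, adjusted p = 1.82e-09), and Stmn2, a microtubule regulator of growing neurons (probe set 10490818), was 20.6-fold higher (4.36, SE 0.12, adjusted p = 6.81e-10). Rtn1, a reticulon of neurons, was 13.5-fold higher and Gria2, a glutamate receptor subunit, was 11.6-fold higher. The imprinted genes Ndn, Mest and Meg3 were 24.5-fold, 19.4-fold and 14.1-fold higher. Sftpc, which encodes surfactant protein C of the lung, was 31.9-fold higher (5.00, SE 0.47, adjusted p = 1.42e-05), and Ttr, the thyroid hormone carrier transthyretin, was 12.2-fold higher. In microgravity minus ground Sftpc was higher by 3.72 without the osteoinductive microgravity array and by 6.28 without the growth microgravity array. The remaining genes of the 12 highest rises were Stox2, Cd24a and Rimklb, at 17.4-fold, 17.8-fold and 14.6-fold. With 32 added before log2 the log2 changes of Ndn, Stox2, Cd24a and Gria2 were 4.02, 3.26, 3.53 and 2.90. Across all genes, 3789 passed the threshold, with 1402 higher and 2387 lower in microgravity.

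Of the 30 tested genes of nervous system development, 17 rose and 5 fell in microgravity against ground (18 and 6 adjusted over the list alone), with a median log2 change of 0.53. The neuronal migration gene Dcx rose by 3.10, the transcription factor Sox11 by 2.79 and the neuronal tubulin Tubb3 by 2.46. The shift of the list relative to other genes had an adjusted p of 2.9e-10 by camera, and adjusted p = 0.565 with an estimated correlation. Markers of other tissues moved with these genes. In lists written after the data were seen, 22 of 22 neuronal and 16 of 17 skeletal muscle markers were higher in the 4 flight arrays than in the 4 ground-based arrays, with median log2 changes of 1.64 and 1.41. In the same comparison 7 of 18 lung epithelium markers were higher, with a median of 0.53, which was 0.28 without the osteoinductive microgravity array. These markers and the sex-linked genes were fitted without the filter on dim genes, over 19938 genes, and the Y-linked genes lay below the filter on every array. Of the Y-linked genes, Eif2s3y was higher by 1.41 (SE 0.17, adjusted p = 7.24e-05), Uty by 0.59 (adjusted p = 0.00506) and Kdm5d by 0.34 (adjusted p = 0.0264), while Usp9y and Zfy1 had adjusted p = 0.36 and adjusted p = 0.458. Xist, expressed from the inactive X chromosome, differed by 0.20 (adjusted p = 0.25).

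**Figure D2:**
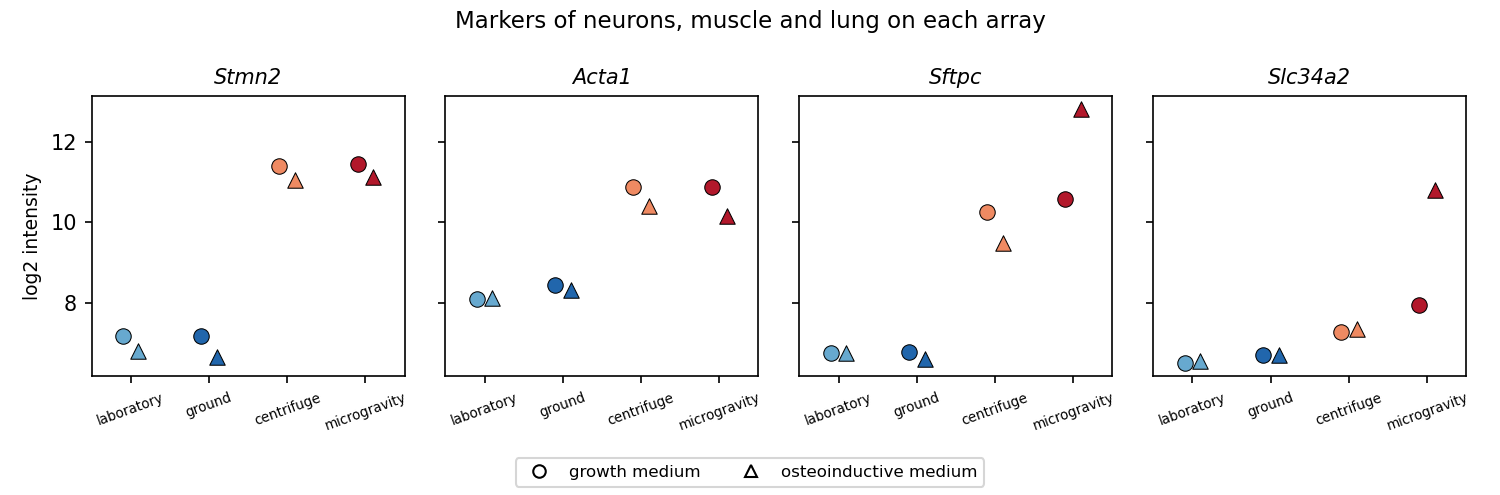
Log2 intensity of the neuronal gene Stmn2, the skeletal muscle gene Acta1 and the lung genes Sftpc and Slc34a2 on each of the 8 arrays, with circles for growth medium and triangles for osteoinductive medium. Stmn2 lay between 11.06 and 11.44 in the flight arrays and between 6.66 and 7.19 in the ground-based arrays, and Slc34a2 reached 10.8 in the osteoinductive microgravity array alone.

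Cartilage and endothelial genes also rose in microgravity against ground. Of 16 chondrocyte genes, 10 rose and none fell (11 and 2 adjusted over the list alone), among them Col2a1, the main cartilage collagen, by 1.11 and Acan, the proteoglycan aggrecan, by 0.95. Of 14 endothelial genes, 12 rose (13 adjusted over the list alone), including Pecam1 by 1.42 and Kdr, a receptor for vascular endothelial growth factor, by 1.33. The adjusted p of the lists was 1.1e-05 and 1.5e-09, and for each list adjusted p = 0.565 with an estimated correlation. Without the osteoinductive microgravity array, which held the highest Sftpc level, the endothelial median in microgravity minus ground was 0.42 in place of 0.71. Under the stricter filter on dim genes the chondrocyte list no longer passed (adjusted p = 0.0557), with a median of 0.29 in place of 0.49.

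Genes of DNA replication and mitosis were lower in microgravity. Of 30 cell cycle genes, 29 fell and none rose (29 adjusted over the list alone), with a median log2 change of -1.07. The spindle checkpoint kinase Bub1 (probe set 10487480) fell by 1.95 (SE 0.17, adjusted p = 7.49e-06) and its partner Bub1b by 1.48. The mitotic motor proteins Cenpe, Kif11 and Kif23 fell by 1.93, 1.80 and 1.72, and Anln and Ect2, which act in cytokinesis, by 1.88 and 1.73. Cip2a and Dbf4, an activator of a replication kinase, fell by 1.86 and 1.66, although Dbf4 did not pass with no term for medium (adjusted p = 0.0549). The shift of the list had an adjusted p of 3.5e-15, and adjusted p = 0.565 with an estimated correlation. The 1000 genes that were brightest in the ground-based arrays had a median log2 change of -0.22 between flight and ground-based arrays, and 411 of them fell while 11 rose.

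Several stress and structural groups fell in microgravity against ground. Of 22 genes of the unfolded protein response, 20 fell (22 adjusted over the list alone), with Sdf2l1 falling by 1.65, Creld2 by 1.64 and Ddit3 by 1.30. Of 21 interferon-stimulated genes, 19 fell (20 adjusted over the list alone), with a median of -0.77. Of 20 antioxidant genes, 11 fell (12 fell and 1 rose adjusted over the list alone), including Hmox1, a haem-degrading enzyme, by 1.19. Among 29 genes of the actin cytoskeleton, 15 fell and 1 rose (19 and 1 adjusted over the list alone), led by smooth muscle actin Acta2, which fell by 1.59 (SE 0.20, adjusted p = 0.00016). Rny1, a small non-coding RNA in none of the lists, fell by 1.74. Of 21 ribosomal protein genes 11 fell (14 adjusted over the list alone), and of 29 respiratory chain genes 5 fell (4 adjusted over the list alone). All of these lists were called lower by camera, the last with an adjusted p of 0.034, and for each list adjusted p = 0.565 with an estimated correlation. Among random lists matched on mean expression, the respiratory median in microgravity minus ground lay at percentile 82.6 in growth medium and 10.3 in osteoinductive medium, so it did not stand apart in either, and the ribosomal median at 42.4 and 1.06. The medians of the other 4 lists lay at or below percentile 0.92 in both media. After quantile normalization the ribosomal and respiratory lists no longer passed (adjusted p = 0.117 and 0.608), and the respiratory list also did not under the stricter filter (adjusted p = 0.319). The cytoskeletal median was -0.21 after quantile normalization, in place of -0.37. The count of 3789 genes in microgravity minus ground became 1377 without the growth microgravity array, 1851 without the growth ground array and 1481 without the osteoinductive ground array.

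The comparison of the centrifuge with the ground hardware asked what changed in flight when both sides were at 1g. Neuronal genes led the rises, with Gpm6a 22.3-fold higher (4.48, SE 0.15, adjusted p = 2.78e-09) and Stmn2 19.7-fold higher (4.30, SE 0.12, adjusted p = 8.08e-10). Stox2, Rtn1 and Rimklb were 15.4-fold, 12.4-fold and 12.3-fold higher, and the log2 change of Stox2 was 3.10 with 32 added before log2. Mitotic genes led the falls, with Bub1 lower by 4.79-fold (adjusted p = 3.1e-06), Ect2 by 3.76-fold, Cip2a by 3.6-fold, the mitotic kinase Plk1 by 3.36-fold and Cenpe by 3.17-fold. In all, 1336 genes passed, 837 higher and 499 lower on the centrifuge.

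Among the lists in the centrifuge minus ground comparison, 15 of 30 genes of nervous system development rose and 2 fell (19 and 4 adjusted over the list alone), and 27 of 30 cell cycle genes fell (27 adjusted over the list alone). The unfolded protein response had 12 of 22 genes lower (15 adjusted over the list alone), and interferon-stimulated genes had 5 of 21 lower (10 adjusted over the list alone). Within single media the median of the interferon list was -0.09 in growth medium and -0.85 in osteoinductive medium, at percentiles 9.92 and 0 of matched random lists, a difference between media that was not tested. The nervous system and cell cycle lists had adjusted p = 0.638 with an estimated correlation, and the unfolded protein response and interferon lists had adjusted p = 0.661 with an estimated correlation. Camera called 9 of 28 lists, 4 higher and 5 lower, but none with an estimated correlation. Among them were the chondrocyte and endothelial lists, higher (adjusted p = 8.12e-05 and 2.06e-05), and the cytoskeletal list, lower (adjusted p = 5.74e-06). Under the stricter filter the chondrocyte list did not pass (adjusted p = 0.218). The cytoskeletal list was not called in microgravity minus centrifuge (adjusted p = 0.438). The count of genes was 2087 without the growth centrifuge array, 726 without the osteoinductive centrifuge array, 796 without the growth ground array and 643 without the osteoinductive ground array. It was 641 under a stricter filter on dim genes.

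Microgravity against the centrifuge was meant to compare gravity within the same flight hardware. With 1 array per medium on each side it also carries differences between single arrays, such as the lung genes of the osteoinductive microgravity array. No gene passed the threshold of limma, the smallest adjusted p being 0.187, although 1507 genes had an unadjusted p under 0.05 where chance alone would give 660. The error was shared by all comparisons between conditions and may be too small for this one, so the excess cannot be read as an effect. Differences between the same 2 conditions in growth and in osteoinductive medium had a correlation of 0.0758 across genes, which are not independent replicates. None of the following genes passed with all 8 arrays in the fit. The highest by rank were Mir680-2 (0.73), the phosphate transporter Slc34a2 (2.05, SE 0.51), Nrsn1 (0.82), Macrod2 (0.89), Mir680-1 (0.72), Mest (1.05, SE 0.19), Clic5 (0.80), the epithelial keratin Krt8 (0.72), Tspan2 (1.08), Bmp5 (0.59), Cops6 (0.76) and Lmo2 (0.50). The lowest were the respiratory chain subunits Cox6b1 (-0.77) and Uqcrh (-0.53), Steap1 (-0.81), Snora23 (-0.78), Ly96, a partner of a bacterial lipid receptor (-0.76), Tnfrsf12a (-0.58), Ssr4 (-0.64), Ifi207 (-0.69), Nr2c2ap (-0.60), C1ra (-0.68), Snord104 (-0.78) and Trappc2l (-0.57). Of these 24 genes 16 passed when only the 4 arrays of both conditions entered the fit, and 14 without either laboratory array. The genes had been chosen for differences of the same sign and large size in both media, which are what the fit of 4 arrays tests. Their passing there is therefore no independent support. Several values rested on single arrays. Without the osteoinductive microgravity array Slc34a2, Mir680-1, Clic5 and Tspan2 were higher by 0.64, 0.45, 0.48 and 0.61, and Cops6 by 1.29. Without the growth microgravity array Slc34a2 was higher by 3.46 and Cops6 by 0.23, and without the osteoinductive centrifuge array Mest was higher by 0.63.

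In microgravity minus centrifuge 13 of 28 lists were called, 3 higher and 10 lower, without any member passing the threshold over all genes. Besides the lists detailed below, chondrocyte and nervous system genes were called higher. Respiratory chain, p53, lysosome, interferon, antioxidant, hypoxia and matrix protease genes were called lower. Quantile normalization or the stricter filter ended all of these further calls except those of the respiratory chain and p53 lists. The ribosomal list had a median of -0.28 with 9 of 21 genes lower adjusted over the list alone, the unfolded protein response -0.26 with 3 of 22, and the immediate early genes -0.20 with 4 of 22. The endothelial list had a median of 0.36 with 5 of 14 higher adjusted over the list alone. For the ribosomal, unfolded protein response, immediate early and endothelial lists adjusted p = 0.569 with an estimated correlation. Among matched random lists the ribosomal median lay at percentile 35.3 in growth medium, where it did not stand apart, and at 0 in osteoinductive medium, and the endothelial median at 45.8 and 100. That of the unfolded protein response lay at 0.91 and 3.53, so it did not pass the bound of 2.5 in osteoinductive medium. That of the immediate early genes lay at 0.77 and 0.19. The endothelial median was 0.07 in growth medium and 0.57 in osteoinductive medium, and it was 0.08 in the fit without the osteoinductive microgravity array. The immediate early median was -0.34 without that array, and after quantile normalization the ribosomal median was -0.16 and that of the unfolded protein response -0.135. In the osteoinductive pair the lung markers Sftpc, Slc34a2 and Scgb1a1 were higher in microgravity by 3.31, 3.45 and 3.53, against 0.30, 0.65 and 0.88 in the growth pair, with 1 array on each side. The count of 0 genes became 47 without the growth microgravity array, 25 without either laboratory array, 3 without the osteoinductive microgravity array, and 49 when only the 4 arrays of both conditions entered the fit.

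**Figure D3:**
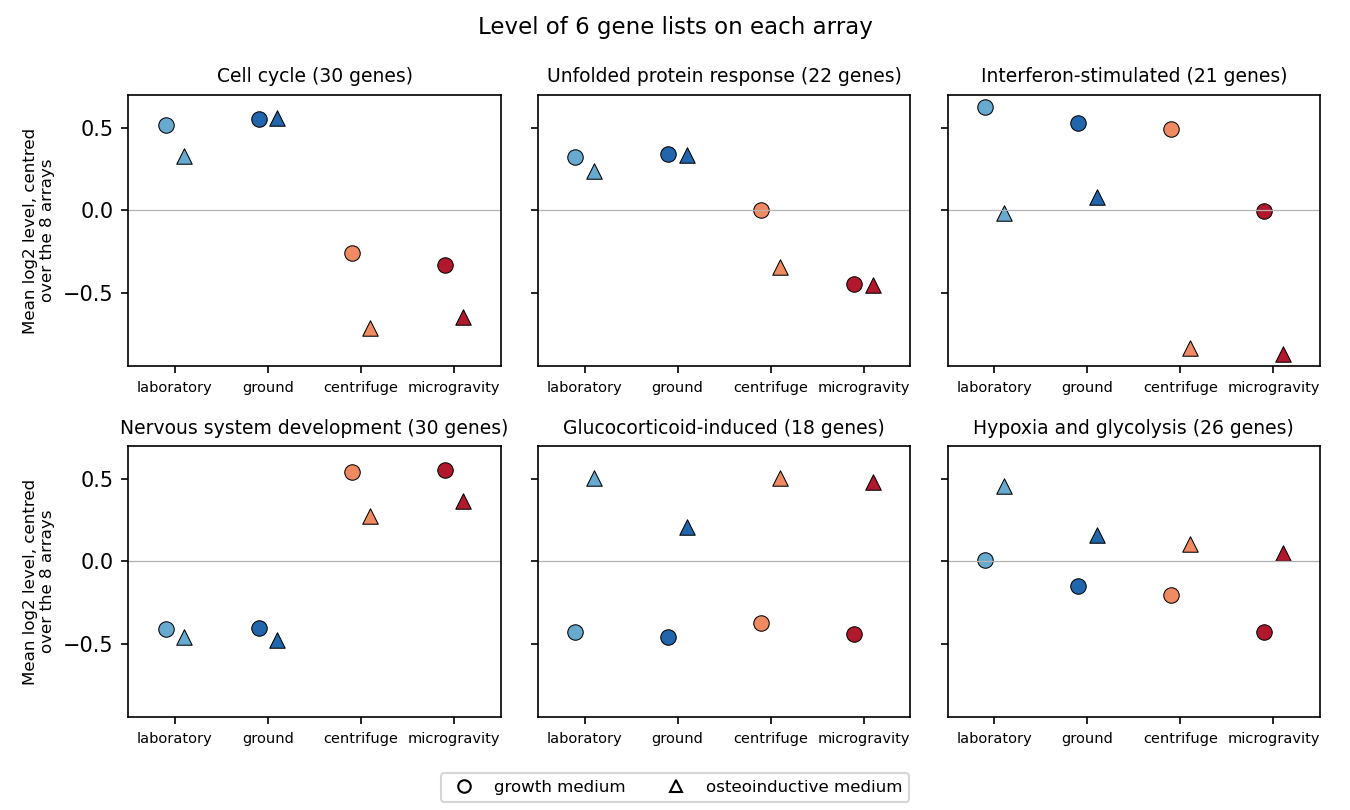
Mean log2 level of 6 gene lists on each of the 8 arrays, centred over the arrays, with circles for growth medium and triangles for osteoinductive medium. Cell cycle levels lay between 0.331 and 0.555 in the ground-based arrays and between -0.712 and -0.26 in the flight arrays, while glucocorticoid-induced genes separated by medium.

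The ground hardware was compared with culture dishes to see what the incubation unit changed at 1g. No gene passed in limma, with a smallest adjusted p of 0.441 and 269 genes at an unadjusted p under 0.05, fewer than the 660 that chance alone would give. Across genes the differences had standard deviations of 0.145 in growth and 0.154 in osteoinductive medium. Those of microgravity minus centrifuge had 0.283 and 0.218. The error was shared by both comparisons and may be too large here, so the count cannot be read against 660. Bnip3, a hypoxia-induced mitochondrial gene, had the smallest adjusted p and a log2 change of -0.74 (SE 0.12). The others by rank were Nrn1 (-0.63), Spred2 (-0.55), Try5 (-0.56) and Syt1 (-0.61), and on the higher side Ppp2r2b (0.54), Rny1 (0.57), Baiap2l1 (0.53), Hs3st3b1 (0.39) and Ect2 (0.37). The list of hypoxia and glycolysis had a median of -0.20 and 4 of 26 genes lower adjusted over the list alone, and the cell cycle list had a median of 0.12 with none past the threshold. Camera at the preset correlation called the hypoxia list lower (adjusted p = 1.65e-11) and the cell cycle list higher (adjusted p = 3.48e-09). Both had adjusted p = 0.867 with an estimated correlation. Camera called 8 of 28 lists in ground minus laboratory, 3 higher and 5 lower, but none with an estimated correlation. The others were the unfolded protein response and chondrocyte lists, higher, and the glucocorticoid, lysosome, respiratory chain and heat shock lists, lower. Quantile normalization ended the chondrocyte call. With only the 4 arrays of both conditions in the fit, 9 genes passed, and 6 of the 10 genes named here were past the threshold. These 10 had been chosen for differences of the same sign and large size in both media, so that is no independent support. Without the osteoinductive ground array the log2 changes of Nrn1, Try5, Rny1 and Ect2 were -0.97, -0.26, 0.30 and 0.20, and without the growth ground array those of Nrn1 and Try5 were -0.30 and -0.86. Without the osteoinductive laboratory array Nrn1, Try5 and Syt1 had -0.42, -0.895 and -0.34, and without the growth laboratory array Try5 and Ect2 had -0.23 and 0.235.

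All flight arrays were then set against all ground-based arrays, 4 on each side, with the different conditions on a side counted as repeats. Gpm6a was higher in flight by 4.53 (SE 0.11, adjusted p = 4.39e-11), Stmn2 was 19.7-fold higher, Sftpc 16.7-fold, Cd24a 16.6-fold and Rtn1 14.3-fold. Without the osteoinductive microgravity array Sftpc was higher by 3.32 in place of 4.06, and with 32 added before log2 Cd24a was higher by 3.41 in place of 4.06. Bub1 fell by 1.94 (SE 0.15, adjusted p = 1e-06), Anln by 1.71, Cip2a by 1.69, Acta2 by 1.65 and Kif11 by 1.51. Of 13205 genes, 5068 passed, with 1675 higher and 3393 lower in flight. In the lists, 28 of 30 cell cycle genes fell (29 adjusted over the list alone), 21 of 22 genes of the unfolded protein response fell (21 adjusted over the list alone), and 21 of 21 interferon-stimulated genes fell (21 adjusted over the list alone). The fall of the interferon genes was uneven. Their mean level, centred over the 8 arrays, was 0.491 on the growth centrifuge array, near 0.53 and 0.622 on the growth ground and laboratory arrays. It was -0.004 on the growth microgravity array, and -0.833 and -0.868 on the osteoinductive centrifuge and microgravity arrays. Among 30 genes of nervous system development 19 rose and 5 fell (21 and 5 adjusted over the list alone). By camera at the preset correlation these lists had, in that order, adjusted p = 3.79e-15, 5.92e-08, 3.44e-06 and 2.4e-11. With an estimated correlation they had adjusted p = 0.41, 0.599, 0.62 and 0.206. Camera called 8 of 28 lists in flight minus ground-based, 3 higher and 5 lower, but none with an estimated correlation.

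The comparison of media asked how osteoinductive medium changed the cells over the 4 conditions. Trf, the iron carrier transferrin (probe set 10596148), was 18.0-fold higher (4.17, SE 0.11, adjusted p = 4.79e-10), Ctla2a 18.1-fold and the protease inhibitor Serpina3n 16.1-fold. The aldehyde dehydrogenases Aldh1a1 and Aldh1a7 were 8.71-fold and 7.39-fold higher, the monooxygenase Fmo2 8.06-fold, Folh1 8.00-fold and the copper-carrying Cp 6.25-fold. Ms4a4d, Gprc5b and the matricellular gene Ccn2 were 5.27-fold, 4.19-fold and 4.26-fold higher. In all 1921 genes passed, 848 higher and 1073 lower in osteoinductive medium.

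Genes induced by glucocorticoids rose with osteoinductive medium, 13 of 18 with none falling (14 adjusted over the list alone) and a median of 0.77. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 2.38 (SE 0.11, adjusted p = 5.16e-08), Tsc22d3 by 1.66 and the metallothionein Mt2 by 1.55. Of 26 genes of hypoxia and glycolysis 14 rose (18 adjusted over the list alone), including Egln3 by 1.22 and Bnip3 by 1.12. Of 17 matrix proteases and their inhibitors 9 rose and 1 fell (13 and 2 adjusted over the list alone), led by Adamts5 at 1.18 and Adamts1 at 1.15. Of 26 matrix genes 10 rose and 3 fell (10 and 4 adjusted over the list alone), with Postn rising by 1.39 and Tnc falling by 1.12. Of 16 adipocyte genes 6 rose (6 adjusted over the list alone), among them Cebpd by 1.19 and the fatty acid carrier Fabp4 by 1.11. The matrix median was 0.06 without the osteoinductive microgravity array and 0.09 in the ground-based arrays alone, in place of 0.14, and the adipocyte median was 0.25 under the stricter filter, in place of 0.14. By camera at the preset correlation these lists had, in the order given, adjusted p = 1.4e-17, 4.19e-12, 3.08e-07, 0.00049 and 0.000225. With an estimated correlation they had adjusted p = 0.32, 0.329, 0.534, 0.569 and 0.32. Camera called 15 of 28 lists in osteoinductive minus growth, 9 higher and 6 lower, but none with an estimated correlation. Of 16 osteoblast genes none rose and 1, Tnfrsf11b, fell by 0.37 (1 adjusted over the list alone). Their median was 0.03 and the list was not called (adjusted p = 0.76).

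Interferon-stimulated genes were lower in osteoinductive medium, 18 of 21 with none rising (19 adjusted over the list alone) and a median of -0.86. Ifit3 (probe set 10462618) fell by 2.20 (SE 0.26, adjusted p = 0.00014), the chemokine Cxcl10 by 1.97, Ifit3b by 1.92, Ddx60 by 1.32, Rsad2 by 1.19, Herc6 by 1.11 and Ifit1 by 1.06. In osteoinductive minus growth the changes of Ifit3 and Cxcl10 were -1.41 and -1.23 in the ground-based arrays alone and -3.00 and -2.71 in the flight arrays alone, a difference that was not tested. Of 19 genes of inflammation 11 fell and 2 rose (11 and 2 adjusted over the list alone), including the cyclooxygenase Ptgs2, which fell by 1.27, while Lcn2 was 2.83-fold higher. Of 20 p53 targets 9 fell and 1 rose (13 and 1 adjusted over the list alone). The remaining named falls were Slc14a1 by 1.52, Rgs16 by 1.19, Ier3 by 1.15 and the checkpoint kinase Chek1 by 1.07. With no term for condition, Cxcl10, Ddx60, Herc6 and Slc14a1 did not pass in osteoinductive minus growth (adjusted p = 0.0518, 0.051, 0.0573 and 0.0669), and Slc14a1 changed by -0.96 in the ground-based arrays alone. By camera at the preset correlation the interferon, inflammation and p53 lists had adjusted p = 4.28e-15, 0.00156 and 0.00049. With an estimated correlation they had adjusted p = 0.534, 0.562 and 0.569. In the ground-based arrays alone the interferon median was -0.495 and the p53 median -0.19, in place of -0.86 and -0.30. The inflammation median was -0.16 without a filter on dim genes and -0.49 under the stricter filter, in place of -0.33. In osteoinductive minus growth the count of 1921 genes was 1115 without either centrifuge array, 1475 in the 4 ground-based arrays alone, where 1268 were shared, and 1083 in the 4 flight arrays alone. It was 1128 with every probe set tested and 312 with no term for condition.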

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

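The tests of a shared muscle and neuron source, of neurons alone, of gravity, of lung RNA, of a response in both media, of dilution and of other splits were chosen after the results they bear on had been seen, as were the organ marker lists. The tests of many organs, of a source of another sex, of compression and of scaling were written before their results were seen.

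Signals outside the planned comparisons stood above the ground-based arrays. Skeletal muscle markers were higher in flight by a median of 1.41 (log2), where 2.5% of random lists matched on the mean of the ground-based arrays exceeded 0.174, and lung epithelium markers by 0.53, where 2.5% exceeded 0.154. The lung median was 0.27 in growth medium and 0.84 in osteoinductive medium, and without the osteoinductive microgravity array it was 0.28, where 2.5% of random lists exceeded 0.157. The Y-linked gene Eif2s3y was higher by 1.41, with 6.09 to 7.10 in the flight arrays and 5.09 to 5.50 in the ground-based arrays, all below the filter on dim genes.

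For the nervous tissue genes, which were higher in all 4 flight arrays, compression of the flight arrays' range is argued against, because quantile normalization left 98.5% of the median change of the neuronal list, and absence of gravity is, because the centrifuge arrays held at least 86.6% of the change in microgravity in both media. A change of the cultured cells towards neurons alone is argued against by 16 of 17 skeletal muscle markers being higher (an earlier form of that test gave 3 of 5 organ lists above 0.25, with heart near that bound). Of 9 organ lists not measured before their test, 1, heart, exceeded random lists, so RNA of many organs is argued against for those 9 alone. The neuronal, muscle and lung lists, which also exceeded random lists, were not among them, so RNA of several organs stays open. RNA from a source with nervous and muscle tissue may account for the nervous tissue genes, since the ratio of muscle to neuron excess differed by a factor of 1.06 (1.057) between the arrays. The ratio of imprinted to neuron excess differed by 1.53, being highest in the osteoinductive microgravity array, which leaves open whether the imprinted genes share that source. A source of another sex or another pool of animals stays open. Of the Y-linked genes Eif2s3y rose by 1.41 (1.413), Uty by 0.59 and Kdm5d by 0.34, while Usp9y and Zfy1 did not pass. This support is weak, because all of these genes lay below the filter on dim genes. Xist lay between 10.48 and 10.97 in the flight arrays and between 10.42 and 10.82 in the ground-based arrays. A broader change of the cultured cells in flight, and the automated hardware that only flight arrays had, were not tested and stay open.

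Lung genes were higher in the osteoinductive microgravity array than in its centrifuge partner. A response to microgravity in both media is argued against, because the lung epithelium median in growth medium was 16.9% of that in osteoinductive medium. RNA of lung tissue in that array may account for it, since a list of endothelial and blood cell genes abundant in lung also rose there, by a median of 1.11 (1.112), while the neuronal, muscle, liver and kidney medians were 0.13, 0.07, 0.01 and -0.04. Of the 13 genes in that list 8 are also in lists fixed earlier. A response limited to osteoinductive medium was not tested, since it has 1 array on each side.

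Cell cycle genes were lower in flight, with median log2 changes of -0.79 in growth medium and -1.05 in osteoinductive medium. Scaling between arrays is argued against, because quantile normalization left 100.8% of the change. Dilution of the cells' RNA by other RNA could not be decided, and the answer depended on the form of the test, of which 3 were run after the data were seen: against random lists the cell cycle list lay lower by -0.73 and -0.97 in the media, and pooled abundant stromal and protease genes changed by 39.1% and 6.9% as much as it did. With each of 4 lists taken alone the shares were 30.5% (stromal), 58.3% (proteases), 47.4% (collagens) and 30.1% (inflammation) in growth medium and 3.8%, 11.6%, 28.8% and 50.4% in osteoinductive medium, so no list fell as much as the cell cycle genes, but dilution may account for part of the fall. A slower cell cycle in flight stays open and was not tested apart from dilution.

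Splits of the 8 arrays into 4 and 4 are too few for a share under 0.05, since only those that keep the arrays of each medium, or of each condition, balanced match the fits. For flight minus ground-based there were 18 such splits, of which 1, the real one, gave 5068 genes and the highest other 0. For osteoinductive minus growth there were 8, of which 1, the real one, gave 1921 genes and the highest other 0. The test was first set, before its result was seen, over all splits that could be fitted, 34 and 32, and those that break this balance are not counted here.

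Of 112 sets of 4 arrays, 8 held an array far from the other 3 in the level of a gene list. A rate of 0.05 would give 5.6 if the 4 arrays of a set were independent draws of one kind. The sets hold different conditions or media and share arrays, and some lists share genes, so the 8 cannot be read against 5.6. These levels are centred over the 8 arrays. The osteoinductive ground array had the lowest adipocyte level (0.087) and glucocorticoid level (0.206) among the osteoinductive arrays, and the osteoinductive microgravity array the highest macrophage level (0.371). The growth centrifuge array had the highest heat shock level (0.102) of the flight arrays, and the growth microgravity array the lowest inflammation level (-0.094) of the growth arrays. Among the ground-based arrays the osteoinductive laboratory array had the lowest level of the unfolded protein response (0.235) and the highest of Wnt and BMP genes (0.053), and the growth laboratory array the highest ribosomal level (0.215).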

How the results depend on the processing

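No named gene changed sign under any alternative run. These genes had been chosen for the same sign in every difference within a medium or condition, so that is no independent support. The medians of 2 lists changed sign as their calls were lost. They were nervous system development in microgravity minus centrifuge under the stricter filter (-0.002) and endothelial genes in osteoinductive minus growth in the ground-based arrays alone (-0.008). Of 102 named gene results 68 were past the threshold, and 63 of these stayed past it in each setting they were tested in, while 5 lost it with no medium or condition term, namely Dbf4 in microgravity minus ground (adjusted p = 0.0549) and Cxcl10, Ddx60, Herc6 and Slc14a1 in osteoinductive minus growth (adjusted p = 0.0518, 0.051, 0.0573 and 0.0669). Of the named gene results that had not passed, 22 did with only the conditions compared and 14 without either laboratory array, all with fewer residual degrees of freedom. The named genes had been chosen by their differences in both media, so these passes are no independent support. Under the stricter filter 48 of the 68 were bright enough to be tested. Quantile normalization gave 3080 genes in microgravity minus ground, 1234 in centrifuge minus ground, 4233 in flight minus ground-based and 2120 in osteoinductive minus growth, and ended 9 of 63 list calls. Counts moved by over 1.5 times as follows, and the cause was not tested. With no medium or condition term the counts were 1295 in microgravity minus ground, 535 in centrifuge minus ground, 3159 in flight minus ground-based and 312 in osteoinductive minus growth. With only the conditions compared, 49 genes passed in microgravity minus centrifuge and 9 in ground minus laboratory. The stricter filter gave 641 in centrifuge minus ground. Every probe set gave 1128, and the flight arrays alone, added after seeing the data, 1083 in osteoinductive minus growth. Leaving out 1 array gave 0 to 47 genes in microgravity minus centrifuge, 1377 to 4695 in microgravity minus ground, 643 to 2087 in centrifuge minus ground, 0 to 0 in ground minus laboratory, 3477 to 6816 in flight minus ground-based and 1115 to 1623 in osteoinductive minus growth. Where the array left out belonged to a condition compared, 1 array of it remained, assumed to vary like the others; in flight minus ground-based and osteoinductive minus growth 3 remained. Of the 63 list calls, the stricter filter ended 12, no filter 3, leaving out the osteoinductive microgravity array 8 and an estimated correlation 63. The ground-based arrays alone ended 5 of the 15 calls in osteoinductive minus growth. Dim probe sets limit what can be seen, and 13205 of 19938 genes lay above the filter.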

Other observations

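The osteoinductive medium also changed groups not described above. Of 24 genes of lysosomes and autophagy 9 rose (12 rose and 1 fell adjusted over the list alone), including the protease Ctsb and the cholesterol transporter Npc1, each by 0.69. Of 18 genes of sterol synthesis 5 fell (7 adjusted over the list alone), with Idi1 falling by 0.61 and Cyp51 by 0.57. Of 17 circadian clock genes 5 rose and 2 fell (7 and 3 adjusted over the list alone), with Per1 and Rora rising by 0.64 each. These lists had adjusted p = 0.534, 0.569 and 0.562 with an estimated correlation, and in osteoinductive minus growth the cholesterol list was not called in the ground-based arrays alone (adjusted p = 0.0524). There the lysosome median was 0.16 in place of 0.24 and the circadian median 0.12 in place of 0.20. The cell cycle and nervous system lists were also called lower by camera in osteoinductive minus growth (adjusted p = 4.98e-05 and 0.0133). The endothelial and cytoskeletal lists were called higher (adjusted p = 0.0133 and 0.0276). None of these calls held in the ground-based arrays alone or with an estimated correlation.

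Of 26 matrix genes 14 fell and 4 rose in flight against ground-based arrays (15 and 4 adjusted over the list alone), with a median of -0.26, and the list was not called (adjusted p = 0.0894; adjusted p = 0.673 with an estimated correlation). It was not called in centrifuge minus ground either (adjusted p = 0.0573), where it had been called lower (adjusted p = 0.0285) before the matching of list names was corrected, after the values had been seen. The following genes of bone, matrix and signalling were chosen after their values were seen. Against ground-based arrays Ibsp, a bone sialoprotein, rose by 1.73 (SE 0.16) and the Wnt antagonist Sfrp2 by 1.54. The elastic fibre gene Eln rose by 1.82, with its highest level, 11.86, on the osteoinductive microgravity array, while Tnc fell by 0.94. The osteoblast list, which holds Ibsp, was not called by camera in flight minus ground-based (adjusted p = 0.0543). It was not called in microgravity minus ground either (adjusted p = 0.101). The list of Wnt and BMP genes, which holds Sfrp2, was not called in flight minus ground-based (adjusted p = 0.698). In lists written after the data were seen, imprinted genes of fetal tissues had the highest median change in flight, 2.34, with 9 of 11 higher and 1 lower, among them Igf2 at 2.60 and Nnat at 3.26. The myelin and astrocyte list had a median of 0.35 and the heart list 0.26. The medians of the liver, pituitary, pancreas, kidney, intestine, skin, lens and retina, testis and erythroid lists lay between -0.03 and 0.16, each below the level that 2.5% of random lists exceeded. Gh, which encodes growth hormone, was higher in flight by 1.53.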
